A study of Mus musculus with 12 samples.

How the data were processed

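The deposited tables hold, per gene and library, RSEM estimated counts as whole numbers and TPM (transcript abundances). Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4, aligned to mm10 with STAR 2.7.1a, and turned by the authors into estimated counts with RSEM 1.2.28. The TPM values were likewise made by the authors with RSEM 1.2.28 and deposited beside the counts. The notes also name DESeq2 1.36.0, the gene annotation and the strand setting of the counting are not stated, and the library kit was a stranded mRNA kit.

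Gene identifiers were matched to GENCODE M21 for symbols, coordinates and overlaps: 55141 of 55487 genes matched (99.4%), and the other 346 held at most 0.0246% of a library's counts. Because RSEM splits reads between similar genes, a gene can hold a count of 0 and a TPM above 0, which was so for 22 to 49 genes per library. A count of 3 was taken as the floor of measurement, which is 0.0894 CPM in the deepest and 0.377 CPM in the shallowest library. That floor covers counting error only.

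Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Groups, comparisons, gene lists, tests and alternatives were fixed before the data were examined. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16836 and removed 38651; the kept genes held at least 99.9% of counts. Counts were scaled by trimmed mean of M values and fitted with edgeR's quasi-likelihood model over all 4 groups (n = 3 each), and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were ipsilateral against contralateral cortex in each genotype, cKO against wt on each side, and the difference of the injury responses. CPM used the scaled library sizes, and log2 CPM a prior count of 2.

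The 31 gene lists covered signalling pathways, leukocytes, brain cell types, stress responses, tissue markers and controls. Some genes were on more than 1 list, so results of different lists are not independent. Dusp1 was among immediate early genes and glucocorticoid targets, and Ptgs2 among NF-kB targets and reactive astrocyte genes. Lists with at least 5 kept members were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Each test was repeated with a correlation estimated from the list and with fry. Named genes followed a fixed rule. Tmem173 and Cx3cr1 were reported in every library. Each comparison added the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and no overlap of CPM between groups, and up to 4 called members per list with the smallest adjusted p. Where nothing was called, the 5 smallest p and up to 3 members per list by mean CPM were given as values. A few genes that this rule names are not reported here.

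Alternatives fixed beforehand were DESeq2 size factors, scaling by library totals, no filter, a strict filter (1 CPM in 3 libraries and a total of 100), the DESeq2 test, limma-voom, limma on log2 TPM with 1 added and a mean of at least 1 TPM, each library left out, the replicate number as a block, and a fit of the 2 compared groups only. Added after the data were seen were fits without cKO ipsilateral library 3, without that library and wt contralateral library 3, and with GC content and gene length trends removed (smoothing span 0.3). Exact permutation tests compared Tmem173 and Cx3cr1 between genotypes.

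The code was tested on simulated counts with known changes. At a true fold of 2 it recovered 85.1% of changed genes in the wt injury comparison, 86.6% in the cKO one, 85.1% and 82.1% between genotypes in ipsilateral and contralateral cortex, and 67.2% for the difference of responses. It made 6 to 11 false calls among unchanged genes per comparison and called 0 of 20 lists without a change. Simulated genes varied independently, and all changed genes were at 1 CPM or more. The list result therefore says nothing about lists whose members move together, and recovery can be lower in real libraries.

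Libraries of different groups carry the same replicate numbers, but nothing in the labels says that equal numbers are the same animal. After group means were removed, ipsilateral and contralateral cKO libraries of equal number correlated at 0.225, 0.312 and 0.233, each being the other's best match. The wt libraries gave −0.233, 0.388 and 0.0298. The fits treat libraries as independent, and the block on replicate number was run as an alternative.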

Results

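RNA was sequenced from the cerebral cortex of mice 2 hr after controlled cortical impact (CCI), a model of traumatic brain injury in which a piston strikes the exposed cortex. Cortex from the side of the impact (ipsilateral) and from the opposite side (contralateral) was collected from mice of 2 genotypes. Per the sample labels, both groups carried a Cx3cr1 allele that encodes a tamoxifen-dependent Cre recombinase, and the group called cKO also carried floxed copies of STING, the adaptor that starts interferon and NF-kB signalling when DNA is found in the cytosol. The series description gives the floxed animals a Cre allele without the tamoxifen-dependent part, and neither source mentions tamoxifen, so how far STING was deleted is not known from them. Cx3cr1 is active in microglia, the resident macrophages of the brain, and in monocytes. The 4 groups held 3 libraries each. Total counts, given as M for 1e6 counts, were 28.3, 28.2 and 27.3 M in wt contralateral libraries 1 to 3, and 24.8, 23.9 and 25.3 M in wt ipsilateral libraries 1 to 3. They were 33.6, 23.1 and 20.8 M in cKO contralateral libraries 1 to 3, and 27.1, 25.7 and 7.96 M in cKO ipsilateral libraries 1 to 3.

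Side of injury was the main difference between libraries: the first principal component (30.7% of the variance) put all 6 ipsilateral libraries above all 6 contralateral ones. cKO ipsilateral library 3, the shallowest, stood apart on the second (14.5%) and held 10548 TPM of the brain noncoding RNA Bc1, looked at after its values were seen, against 83028 to 167036 TPM in the other libraries. wt contralateral library 3 lay furthest out on the third component (9.95%). Levels are means ± SD of the 3 libraries of a group in CPM (counts scaled to library size), log2 fold changes carry their SE, and adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The labels do not say that libraries came from separate animals, so p values measure the spread between these libraries.

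The targeted gene, Tmem173 (Sting1, ENSMUSG00000024349), is a protein-coding gene on chromosome 18 at 35733679 to 35740554 of mm10, minus strand. Its level was low in all groups and lower in cKO cortex. In contralateral cortex it had 2.49, 2.63 and 3.18 CPM (72, 76 and 85 counts) in wt libraries 1 to 3 and 0.998, 1.96 and 0.762 CPM (34, 46 and 16 counts) in cKO libraries 1 to 3. In ipsilateral cortex it had 2.34, 3.69 and 2.72 CPM (57, 86 and 66 counts) in wt and 1.05, 2.44 and 1.24 CPM (29, 61 and 10 counts) in cKO. The log2 difference between cKO and wt was −1.16 ± 0.35 in contralateral cortex (unadjusted p = 0.00479, adjusted p = 1, and 0.00724 with no low-count filter) and −0.84 ± 0.35 in ipsilateral cortex (unadjusted p = 0.032, adjusted p = 0.816). Without the filter, other splits of the contralateral libraries gave 38 to 591 called genes, so the 0.00724 carries little weight. An exact two-sided permutation test gave p = 0.1 for the contralateral side, the smallest that 3 against 3 libraries allow, and p = 0.2 for the ipsilateral side, where cKO library 2 lay above the lowest wt library. All 12 libraries kept reads of the gene; the counts are per gene, and the labels do not say which exons are floxed. Tmem173 did not differ between sides past the test in wt (0.08 ± 0.33, adjusted p = 0.944) or cKO (0.39 ± 0.38, adjusted p = 0.684).

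**Figure D1:**
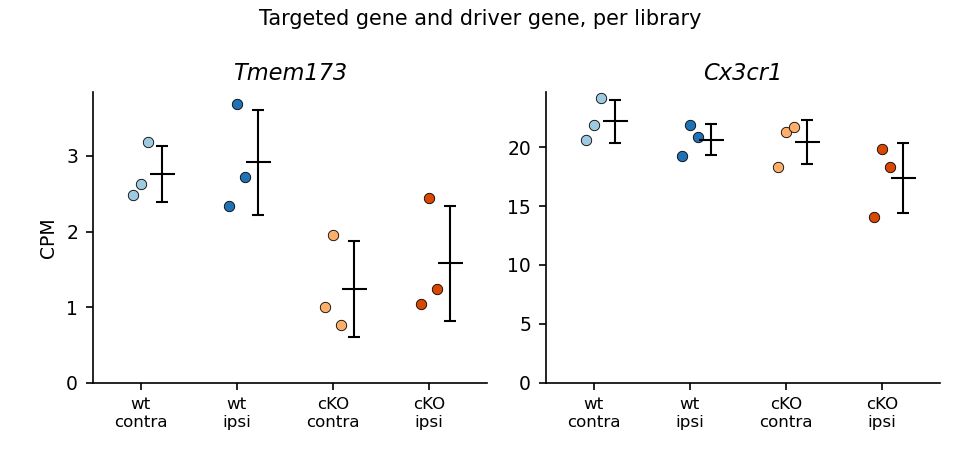
Level of Tmem173 and Cx3cr1 in CPM in each of the 12 libraries by group, with the mean and SD of each group. Tmem173 means are 2.76 and 2.91 CPM in wt contralateral and ipsilateral cortex and 1.24 and 1.58 CPM in cKO, and Cx3cr1 means lie between 17.4 and 22.2 CPM.

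Cx3cr1 (ENSMUSG00000052336, chromosome 9 at 119901616 to 120069879, minus strand), the fractalkine receptor gene whose locus drives the Cre, was at 22.2 ± 1.83 CPM in wt contralateral and 20.6 ± 1.30 CPM in wt ipsilateral cortex. It was at 20.4 ± 1.85 CPM in cKO contralateral and 17.4 ± 2.97 CPM in cKO ipsilateral cortex. The genotypes differed by less than the test could resolve on either side (exact two-sided permutation p = 0.4 contralateral and 0.2 ipsilateral). The gene overlaps Gm33858 on the opposite strand, and since the strand setting of the counting is not stated, its counts may include reads of that gene.

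The first comparison sets the injured against the opposite side of wt cortex at 2 hr, and this difference between sides is called the injury response. The samples hold no sham-operated or uninjured mice. Surgery on the injured side therefore cannot be told apart from the impact, and changes shared by both sides are missed. Immediate early transcription factors, pro-inflammatory cytokines, chemokines that attract neutrophils and monocytes, and transcripts of neutrophils themselves were higher on the injured side. Atf3, a stress-induced transcription factor, rose from 2.18 ± 0.184 to 45.6 ± 5.2 CPM (log2 4.39 ± 0.19, adjusted p = 9.52e-09). The cytokine gene Il1a rose from 1.11 ± 0.601 to 49.8 ± 7 CPM (log2 5.49 ± 0.43, adjusted p = 1.4e-06). S100a9, a subunit of the neutrophil protein calprotectin, rose from 0.200 ± 0.0699 to 6.28 ± 3.50 CPM (log2 4.93 ± 0.52, adjusted p = 2.95e-05). In all, 460 genes rose and 31 fell among 16836 tested, and 211 of the rises but 2 of the falls were at least 2-fold.

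Of 34 immediate early genes, which neurons and glia transcribe within minutes of a stimulus, 30 rose and none fell (camera adjusted p = 4.34e-140; adjusted p = 5.09e-05 with an estimated correlation). Fos went from 46.8 ± 9.14 to 341 ± 15 CPM, Fosb gained 3.22 ± 0.21 and Btg2 2.02 ± 0.13 on the log2 scale. The 4 that did not pass were Homer1, Egr3, Bdnf and Klf2. Of 29 cytokines and NF-kB targets, 21 rose (adjusted p = 0.000292 with an estimated correlation). These included Nfkbiz (log2 3.07 ± 0.15, adjusted p = 1.5e-08), a nuclear cofactor of NF-kB, and the feedback inhibitors Socs3 (2.48 ± 0.15) and Tnfaip3 (2.23 ± 0.15). Il1b went from 0.616 to 9.97 CPM (4.01 ± 0.28, adjusted p = 5.37e-07).

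Of 14 measured chemokines, 10 rose (adjusted p = 0.00103 with an estimated correlation). The macrophage inflammatory proteins Ccl3 and Ccl4 rose by 5.06 ± 0.42 and 5.44 ± 0.41, to 27.4 ± 3.26 and 18.1 ± 2.34 CPM. Cxcl1 and Cxcl2, ligands of the neutrophil receptor Cxcr2, rose by 4.36 ± 0.40 and 4.94 ± 0.45, to 6.16 and 8.51 CPM. Of 15 measured neutrophil markers, 12 rose (adjusted p = 0.0452 with an estimated correlation), and the list's median log2 change was 4.26 with members absent from contralateral libraries held at their lower bound. S100a8, the partner of S100a9, rose by 4.37 ± 0.71 (adjusted p = 0.00231). Trem1, a receptor of neutrophils and monocytes, was at 1.21 ± 0.813 CPM against 0.0115 CPM contralaterally, and Clec4d, a lectin of myeloid cells, at 0.772 against 0.0470 CPM; both rose past the test (adjusted p = 0.00153 and 0.005), but the contralateral counts were too few for a fold. Ppbp, a chemokine stored in platelets, was at 2.34 ± 1.35 against 0.0230 CPM (adjusted p = 7.91e-05).

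Transcripts of the vessel wall and of reactive astrocytes moved the same way. Endothelial activation genes rose in 8 of 19 cases (adjusted p = 0.00276 with an estimated correlation), among them the leukocyte adhesion molecule Icam1 (log2 2.98 ± 0.23), the protease Adamts1 (2.19 ± 0.16) and the urokinase receptor Plaur (2.99 ± 0.25). Of 24 reactive astrocyte genes 7 rose (adjusted p = 0.0158 with an estimated correlation), led by the lipopolysaccharide coreceptor Cd14 (3.39 ± 0.23), which myeloid cells also make, Emp1 (2.62 ± 0.21) and the prostaglandin synthase Ptgs2 (2.2 ± 0.18). Of 15 astrocyte markers 6 rose (adjusted p = 0.0475 with an estimated correlation), including the transcription factor Sox9 (0.87 ± 0.14). Of 17 inflammasome and cell death genes 3 rose (adjusted p = 0.025 with an estimated correlation), with the sensor Nlrp3 at 3.77 ± 0.30 and the caspase Casp4 at 2.2 ± 0.39.

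Of 13 genes encoded by the mitochondrial genome, 10 rose over all genes and 13 adjusted over the list alone (median log2 0.78; adjusted p = 0.0158 with an estimated correlation). mt-Co2 rose by 1.53 ± 0.14 (adjusted p = 7.58e-06). All genes with an mt- symbol took 7.68% ± 0.673 of counts in ipsilateral against 4.76% ± 0.601 in contralateral wt libraries. This mitochondrial share includes genes outside the list of 13, such as the rRNA gene mt-Rnr1. Red cell transcripts were also higher. Hemoglobin genes summed to 1336 ± 727 CPM against 103 ± 126 CPM, and Alas2, an enzyme of heme synthesis in erythroid cells, rose by 3.57 ± 0.59 (adjusted p = 0.00248). The erythroid list had 3 of 10 members up, and its camera call (adjusted p = 0.000643) was lost with an estimated correlation (adjusted p = 0.202). RSEM divides reads between near-identical hemoglobin genes, so single values of that family are uncertain. Whether the neutrophil transcripts came from blood in the tissue or from cells that had entered it was not tested.

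Other lists were called by camera with its preset correlation but not with an estimated one. fry, which called 19 of 31 lists in wt, also called the heat shock (adjusted p = 0.016), glucocorticoid (0.0401), stress response (0.00853), circadian (0.00484) and disease-associated microglia lists (0.0421), but not the monocyte list (0.0714). Heat shock genes rose in 5 of 16 cases, led by Hspa1b (1.66 ± 0.23) and Hspa1a (1.54 ± 0.23), near-identical chaperone genes whose reads RSEM has to divide (adjusted p = 0.152 with an estimated correlation). Of 20 glucocorticoid targets 6 rose, including the phosphatase Dusp1 (1.25 ± 0.12), and 1 fell (adjusted p = 0.21 with an estimated correlation). Dusp1 is also on the immediate early list, and the target that fell was Fkbp5 (values given below). Of 17 unfolded protein and integrated stress response genes 2 rose, with Ppp1r15a, which restores translation after stress, at 1.44 ± 0.10 (adjusted p = 0.0965 with an estimated correlation). The clock gene Per1 (0.72 ± 0.08) was among 4 of 16 circadian genes that rose (adjusted p = 0.0965 with an estimated correlation). Of 17 monocyte and macrophage markers 3 rose, among them Thbs1 (2.30 ± 0.26), which platelets also carry (adjusted p = 0.335 with an estimated correlation). Of 16 disease-associated microglia genes 2 rose (adjusted p = 0.291 with an estimated correlation). Camera's calls of oligodendrocyte precursor markers, striatal markers, and endothelial and mural cell markers (adjusted p = 0.302, 0.484 and 0.551 with an estimated correlation) were lost without wt contralateral library 1 or wt ipsilateral library 2 (highest camera adjusted p = 0.157, 0.365 and 0.598). The striatal call was also lost without wt contralateral library 2 or wt ipsilateral library 1, and the endothelial one without wt contralateral library 2, wt ipsilateral library 3 or cKO ipsilateral library 3.

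The falls were small. Tmem119, a marker of homeostatic microglia, fell from 25.1 ± 1.77 to 15.4 ± 2.43 CPM (log2 −0.71 ± 0.13, adjusted p = 0.00564), the only member of its list of 22 to pass (list adjusted p = 0.323). The other named falls were the apoptosis gene Bmf (−1.05 ± 0.22), the matrix gene Ccn2 (−0.95 ± 0.24), Myoc (−0.77 ± 0.18), the meningeal transporter Slc6a13 (−0.70 ± 0.18) and the glucocorticoid receptor chaperone Fkbp5 (−0.62 ± 0.15), with adjusted p of 0.017 to 0.0489. Each of these 5 calls was lost without either wt contralateral library 1 or 2. Each was also lost without some ipsilateral library: Bmf without 1 or 3, Ccn2 without 2 or 3, Myoc and Slc6a13 without 1 or 2, and Fkbp5 without any one of the 3. Ccn2 was lost without wt contralateral library 3 as well, and Slc6a13 without cKO ipsilateral library 3, and the highest adjusted p were 0.102 for Bmf, 0.214 for Ccn2, 0.157 for Myoc, 0.193 for Slc6a13 and 0.192 for Fkbp5. All 15 meningeal and fibroblast markers were below 0 (median −0.43, camera adjusted p = 2.26e-07; adjusted p = 0.234 with an estimated correlation), and Slc6a13 was the one that fell.

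No member of the type I interferon list passed in wt (0 of 29 with edgeR, also adjusted over the list alone; camera adjusted p = 0.212). Cmpk2 was at −0.15 ± 0.10. Some interferon-inducible genes outside the list, chosen after their values were seen, did rise in wt and in cKO: Slfn2 (1.5 ± 0.19 and 1.74 ± 0.20), Irf1 (0.89 ± 0.17 and 1.34 ± 0.17) and Plscr1 (0.94 ± 0.21 and 0.84 ± 0.21). None of the 14 STING pathway genes passed either (camera adjusted p = 0.347), with the kinase Tbk1 at −0.13 ± 0.08. The number of calls depended on single libraries: it was 250 without wt contralateral library 2, 861 without wt contralateral library 3, 281 without wt ipsilateral library 2 and 310 without wt ipsilateral library 3. DESeq2 called 755 genes, limma on TPM 139, edgeR without the filter 991 and edgeR with GC content and length trends removed 785 (625 up and 160 down), while scaling by library totals gave 379 up and 73 down. The falls alone went from 31 to 2 without wt contralateral library 2, to 10 and 11 without wt ipsilateral library 3 and 2, and to 174 both without wt contralateral library 3 and with DESeq2.

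The same comparison in cKO mice found the same kinds of genes higher on the injured side. Atf3 rose from 1.96 ± 0.611 to 45.8 ± 10.8 CPM (log2 4.55 ± 0.20, adjusted p = 7.06e-09) and Fos from 38.2 ± 4.40 to 298 ± 30.3 CPM (2.96 ± 0.13). Ccl4 was at 18.3 ± 2.32 against 0.0892 CPM (adjusted p = 3.17e-07) and the cytokine gene Tnf at 8.76 ± 2.39 against 0.109 CPM (adjusted p = 2.43e-07), with too few contralateral counts for a fold. Ccl3 rose by 6.99 ± 0.52 and Il1a by 6.28 ± 0.50. The Ccl3 fold is uncertain, because its contralateral level came almost entirely from cKO library 3 (values given below). S100a9 rose from 0.151 to 10.6 ± 4.27 CPM (6.11 ± 0.54, adjusted p = 4.22e-06). In all, 431 genes rose and 30 fell of 16836 tested, with 230 rises and 4 falls of at least 2-fold. The number of falls depended on the test: DESeq2 called 541 rises and 113 falls, and edgeR with GC content and length trends removed 551 and 104. Leaving out 1 library gave 6 falls (without cKO contralateral library 1), 10 (contralateral 2 or ipsilateral 2), 14 (ipsilateral 3), 15 (ipsilateral 1) or 22 (contralateral 3).

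In cKO cortex 29 of 34 immediate early genes rose (adjusted p = 5.93e-05 with an estimated correlation), Nr4a2 being the one called in wt and not here. Of 29 cytokines and NF-kB targets 24 rose (adjusted p = 0.000338 with an estimated correlation), with Nfkbiz at 2.91 ± 0.15, Socs3 at 2.91 ± 0.16 and Il1b at 4.98 ± 0.30. Of 14 chemokines 11 rose (adjusted p = 0.00147 with an estimated correlation). Cxcl1 gained 5.81 ± 0.42, and Cxcl2 reached 10.4 ± 2.91 CPM from 0.0257 CPM (adjusted p = 7.95e-07). Of 15 neutrophil markers 13 rose (median 4.54 with absent members at their bound; adjusted p = 0.0191 with an estimated correlation). Trem1 was at 2.40 ± 1.13 against 0.0317 CPM, Clec4d at 1.67 ± 0.873 against 0.00978 CPM, and Hdc, which makes histamine, rose by 2.61 ± 0.35.

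Endothelial activation genes rose in 12 of 19 cases in cKO (adjusted p = 0.00212 with an estimated correlation), with Icam1 at 3.36 ± 0.23. Of 24 reactive astrocyte genes 7 rose (adjusted p = 0.0103 with an estimated correlation), including Emp1 (3.59 ± 0.22). Heat shock genes rose in 6 of 16 cases (adjusted p = 0.0148 with an estimated correlation), with Hspa1a at 2.14 ± 0.23, Hspa1b at 2.10 ± 0.22 and the cochaperone Bag3 at 0.93 ± 0.12. Of 17 inflammasome and cell death genes 4 rose (adjusted p = 0.0148 with an estimated correlation), with Nlrp3 at 4.06 ± 0.33. Mitochondrially encoded genes rose in 3 of 13 cases over all genes and 11 adjusted over the list alone (median 0.47, camera adjusted p = 3.53e-08; adjusted p = 0.0989 with an estimated correlation). The mitochondrial share, over all genes with an mt- symbol, was 6.2% ± 1.19 of counts in ipsilateral and 4.45% ± 0.279 in contralateral libraries. Hemoglobin genes summed to 757 ± 148 against 31.5 ± 43.3 CPM, and 5 of 10 erythroid genes rose (adjusted p = 0.229 with an estimated correlation). Blood in the tissue was not tested here either as a source of the neutrophil transcripts.

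Further lists called in cKO with the preset correlation and by fry, but not with an estimated correlation, included glucocorticoid targets (8 of 20 rose; adjusted p = 0.0902 with an estimated correlation), monocyte and macrophage markers (5 of 17; 0.103), stress response genes (3 of 17; 0.0689), astrocyte markers (1 of 15; 0.11) and disease-associated microglia genes (3 of 16; 0.23). Their adjusted p by fry were 0.0093, 0.0104, 0.0047, 0.00636 and 0.026. The call of the circadian list (3 of 16; adjusted p = 0.238 with an estimated correlation) was also lost without cKO contralateral library 1 (camera adjusted p = 0.0568). The neuron marker list was called as lower by camera (adjusted p = 0.00175) and fry (0.0181) but not with an estimated correlation (adjusted p = 0.11). Of its 20 members 2 fell: Snap25, a call lost without any one of the 6 cKO libraries (highest adjusted p = 0.143), and Tubb3, lost without cKO contralateral library 3 or ipsilateral library 1 (0.0613). All 15 meningeal markers were below 0 and none passed (median −0.35; adjusted p = 0.327 with an estimated correlation). Of 12 oligodendrocyte precursor markers 1 rose (adjusted p = 0.289 with an estimated correlation), a list call lost without cKO contralateral library 3 (camera adjusted p = 0.095).

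Tmem119 fell in cKO as well, from 22 ± 2.71 to 13.5 ± 1.66 CPM (−0.69 ± 0.13, adjusted p = 0.00797), a call lost without cKO ipsilateral library 1 (adjusted p = 0.0614). Other named falls were Alx4 (−1.20 ± 0.27), the microglial gene Abi3 (−0.75 ± 0.17), Pars2 (−0.63 ± 0.15), the replication gene Gins2 (−0.63 ± 0.16) and the sodium channel subunit Scn4b (−0.56 ± 0.12). All 5 calls were lost without cKO contralateral library 1 or 2 and without cKO ipsilateral library 2, with highest adjusted p of 0.169 for Alx4, 0.166 for Abi3, 0.186 for Pars2, 0.229 for Gins2 and 0.0888 for Scn4b. Alx4, Abi3 and Pars2 were lost without contralateral library 3 too, all but Abi3 without ipsilateral library 3, and Abi3 without ipsilateral library 1.

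The interferon and STING pathway lists again had no called member in cKO (0 of 29 and 0 of 14 with edgeR, also adjusted over the list alone; camera adjusted p = 0.173 and 0.319). Tbk1 was at −0.11 ± 0.08. The total of 461 calls became 280 without cKO contralateral library 1 and 277 without cKO ipsilateral library 2. edgeR without the filter called 968 genes and limma on TPM 174.

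**Figure D2:**
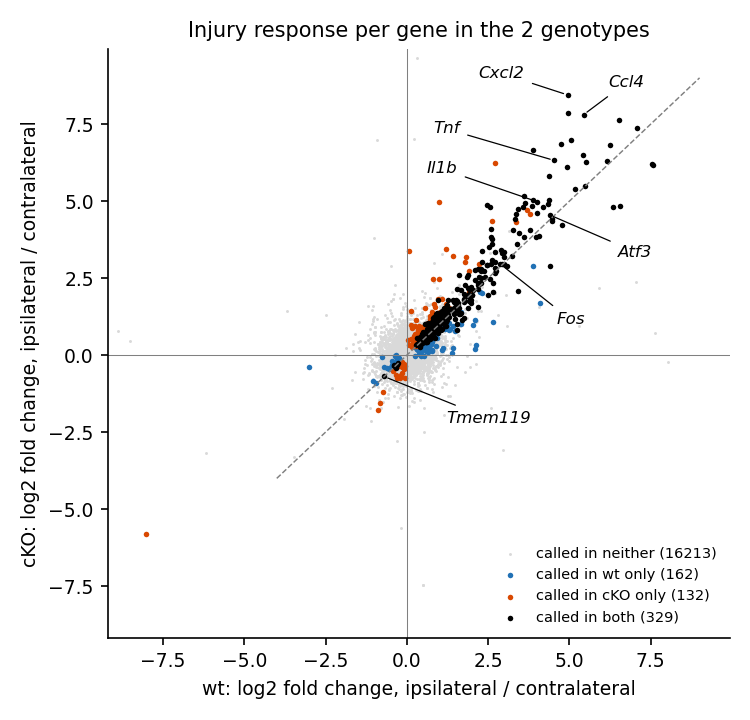
Log2 fold change of each of 16836 genes between ipsilateral and contralateral cortex in wt (horizontal) and cKO (vertical), with genes coloured by where they were called. The 329 genes called in both lie along the dashed line of equal change, and 162 and 132 were called in wt or cKO alone.

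The injury responses of both genotypes overlapped. Of the rises, 322 genes were called in both, 138 in wt alone and 109 in cKO alone, where independent lists of these sizes would share 11.8. Of the falls, 7 were shared, 24 were called in wt alone and 23 in cKO alone, where 0.0552 would be shared. Across the 623 genes called in either genotype, 620 (99.5%) had the same sign in both and Pearson's r of the log2 changes was 0.922; it was 0.658 across all genes. These are correlations across genes, which are not independent replicates, and the comparisons share no library. The 623 genes were picked by their calls in these same comparisons and most rose, which by itself can raise the 99.5% and the 0.922. Being called in one genotype alone is not a difference between them; that difference is tested below.

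**Figure D3:**
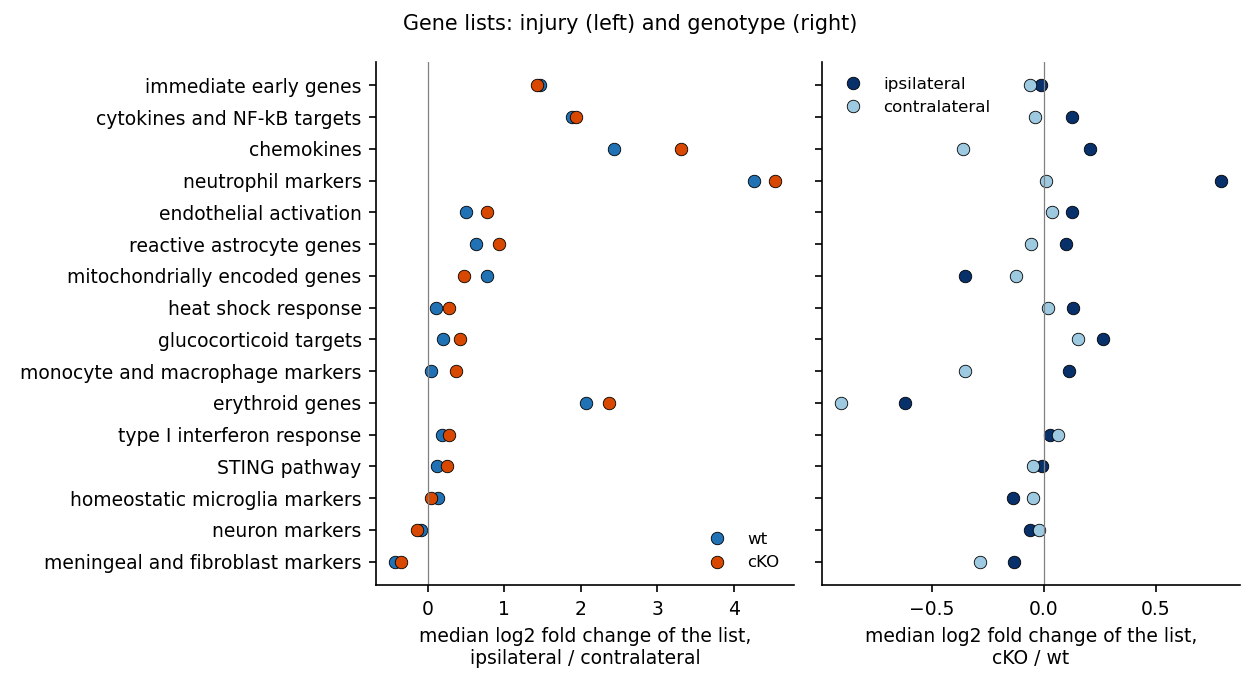
Median log2 fold change of the measured members of 16 gene lists, for ipsilateral against contralateral cortex in each genotype (left, members absent from a group at their bound) and for cKO against wt on each side (right). Neutrophil markers have medians of 4.26 in wt and 4.54 in cKO on the left and 0.79 in ipsilateral cortex on the right.

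The next comparison sets cKO against wt in the injured cortex, where the series title places STING signalling upstream of neutrophil entry. No single gene passed there, and no list was called with an estimated correlation or by fry. With camera's preset correlation glucocorticoid targets were called as higher in cKO (adjusted p = 0.3 with an estimated correlation, 0.295 by fry). Fkbp5 was at 42.3 against 26.6 CPM (log2 0.68 ± 0.15), the lipid droplet gene Plin4 at 7.24 against 3.10 CPM (1.21 ± 0.27) and the metallothionein gene Mt2 at 104 against 76.9 CPM (0.44 ± 0.10). S100a9 was at 10.6 ± 4.27 against 6.28 ± 3.50 CPM (0.79 ± 0.34, adjusted p = 0.818). The neutrophil list was called as higher with the preset correlation only (adjusted p = 0.398 with an estimated correlation, 0.393 by fry), and not without cKO ipsilateral library 2 (camera adjusted p = 0.142) or wt ipsilateral library 1. Mitochondrially encoded and homeostatic microglia genes were called as lower with the preset correlation only (adjusted p = 0.308 and 0.398 with an estimated correlation, 0.356 and 0.374 by fry).

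With edgeR 0 genes passed, 987 had an unadjusted p under 0.05 (5.86%) and the smallest adjusted p was 0.577. The CPM of the groups did not overlap for 11.6% of genes, where chance gives 10% for 3 against 3. limma-voom called 0 genes, limma on TPM 1 and DESeq2 12. Among the smallest p were those of Hif3a, a hypoxia-inducible factor subunit (0.86 ± 0.17, 4.86 ± 0.775 against 2.73 ± 0.389 CPM), the cell cycle inhibitor Cdkn1a (0.41 ± 0.08, 86.9 ± 2.77 against 65.5 ± 3.43 CPM), the kinase Map3k6 (0.69 ± 0.15) and the adhesion receptor Adgrl2 (−0.46 ± 0.10). DESeq2 called these genes (adjusted p = 0.0309 for Cdkn1a and 0.0498 for the others). Its other calls, named after their values were seen, included Plin4, Fkbp5, Dpysl2, Dpysl5 and Gm21541 as higher and Rasd2 and Scn4b as lower. DESeq2 put Gm21541 at log2 23.2 ± 4.25 and edgeR at 9.54 (edgeR unadjusted p = 0.0228), so its fold is not usable. Without the filter edgeR called 223 genes.

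**Figure D4:**
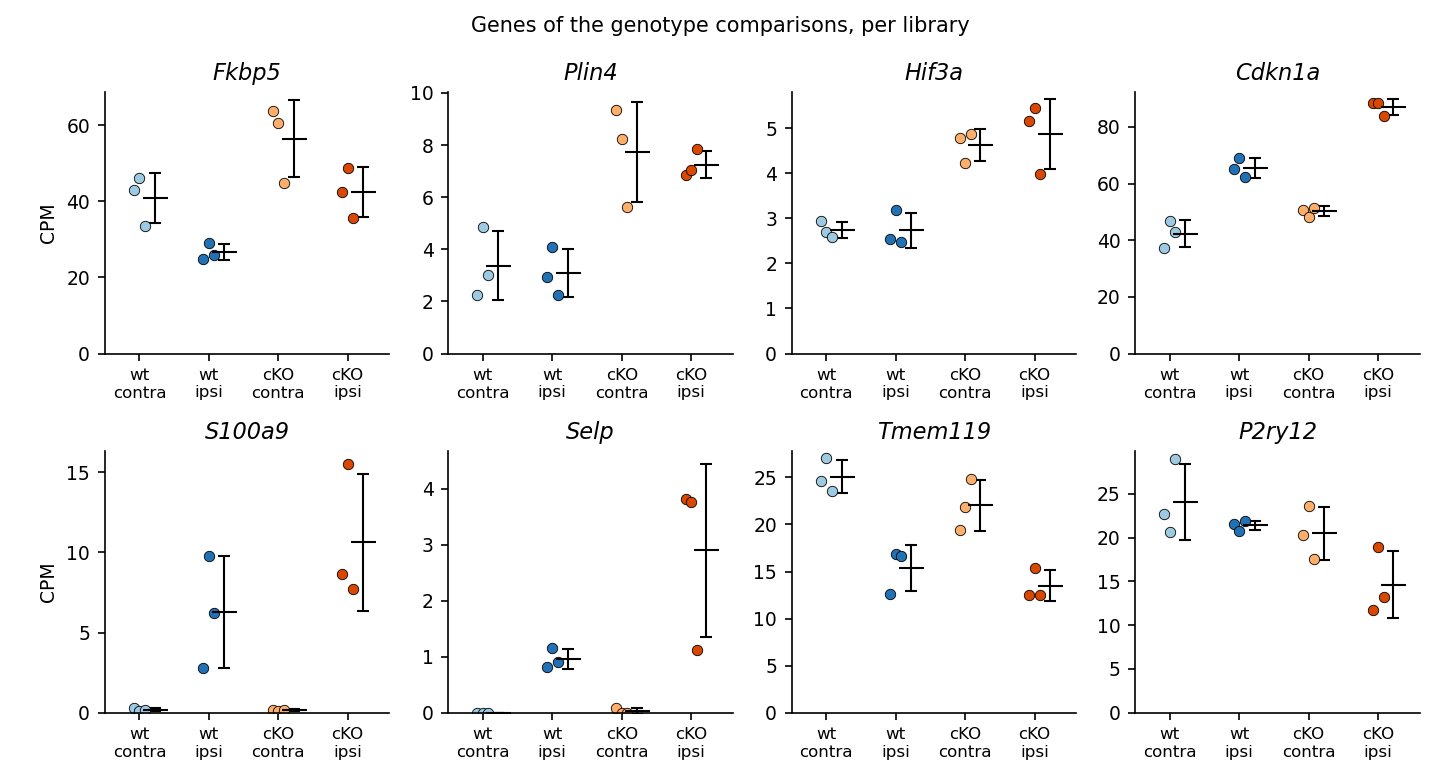
CPM in each of the 12 libraries, by group, of genes with differences between genotypes, with group means and SD. Fkbp5 means are 42.3 CPM in cKO and 26.6 CPM in wt ipsilateral cortex, and S100a9 means are 10.6 and 6.28 CPM.

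In the ipsilateral comparison camera called 14 of 31 lists with its preset correlation, and none with an estimated correlation or by fry. The members named from these lists passed adjusted over the list alone and were chosen after their values were seen. Of 20 glucocorticoid targets 18 were higher in cKO and 9 passed adjusted over the list alone, 0 over all genes (median 0.26, camera adjusted p = 2.52e-12; adjusted p = 0.3 with an estimated correlation). Those 9 included the transcription factor Zbtb16 (0.59 ± 0.15) and Tsc22d3 (0.29 ± 0.08), both classical targets of the receptor. All 16 heat shock genes were higher (median 0.13; adjusted p = 0.254 with an estimated correlation), and Hspa1b (0.90 ± 0.21) and Hspa1a (0.82 ± 0.22) passed adjusted over the list alone. Of 13 mitochondrially encoded genes 11 were lower and 8 passed adjusted over the list alone (median −0.35; adjusted p = 0.308 with an estimated correlation); mt-Atp6 was at −0.49 ± 0.15. Of 22 homeostatic microglia markers 21 were lower (median −0.14; adjusted p = 0.398 with an estimated correlation), and Gpr34 (−0.76 ± 0.20), Slc2a5 (−0.71 ± 0.21) and the purinergic receptor P2ry12 (−0.54 ± 0.17) passed adjusted over the list alone.

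All 15 neutrophil markers were higher in cKO ipsilateral cortex (median 0.79) and 0 passed adjusted over the list alone (camera adjusted p = 2.77e-05; adjusted p = 0.398 with an estimated correlation). The call was lost without cKO ipsilateral library 2 (camera adjusted p = 0.142) or wt ipsilateral library 1. Of 19 endothelial activation genes 14 were higher (median 0.12; adjusted p = 0.398 with an estimated correlation). The call was lost without cKO ipsilateral library 2 (camera adjusted p = 0.127). The list's median lay between 0.16 and 0.18 with each ipsilateral library left out. Those fits kept 17113 to 17228 genes against 16836, so the members can differ and these medians are not directly comparable with 0.12. The selectins Selp (2.90 against 0.961 CPM, 1.67 ± 0.44) and Sele (1.65 ± 0.50), which slow rolling leukocytes, Adamts9 (0.72 ± 0.22) and Icam1 (0.60 ± 0.19) passed adjusted over the list alone. Of 20 neuron markers 18 were lower, with Snap25 at −0.25 ± 0.06 (adjusted p = 0.308 with an estimated correlation; lost without cKO ipsilateral library 1, camera adjusted p = 0.0519). Cytokines and NF-kB targets leaned higher (median 0.13; adjusted p = 0.451 with an estimated correlation), a call lost without wt ipsilateral library 1 or 3 or without cKO ipsilateral library 1 (camera adjusted p = 0.578). Chemokines (camera adjusted p = 0.256), immediate early genes (0.413), interferon genes (0.338) and STING pathway genes (0.428) did not differ past the test, with Ccl3 at 30.5 against 27.4 CPM.

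The other 6 lists that camera called in ipsilateral cortex held mostly tissue and blood markers. Stress response genes were higher in 15 of 17 cases (camera adjusted p = 0.00112; adjusted p = 0.339 with an estimated correlation). The rest leaned lower: striatal markers in 11 of 13 cases (0.398 with an estimated correlation; lost without wt ipsilateral library 2, camera adjusted p = 0.139) and erythroid genes in 10 of 10 (0.398; lost without wt ipsilateral library 2, 0.102, or 3). Endothelial and mural markers were lower in 15 of 18 cases (0.451) and astrocyte markers in 12 of 15 (0.398), both lost without cKO ipsilateral library 1 or wt ipsilateral library 3 (highest camera adjusted p = 0.364 and 0.209). Meningeal markers were lower in 15 of 15 cases (0.528; lost without cKO ipsilateral library 1 or 3 or wt ipsilateral library 3, highest camera adjusted p = 0.888).

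In contralateral cortex, which had not been struck, 0 genes passed between genotypes with edgeR, 455 (2.7%) had an unadjusted p under 0.05, and CPM did not overlap for 7% of genes, where chance gives 10%. The 455 became 841 without wt contralateral library 3. limma-voom and limma on TPM called 0 genes and DESeq2 1, and edgeR without the filter 96. The DESeq2 call was Gm14440, named after its value was seen. DESeq2 put it at log2 21.7 ± 4.25 and edgeR at 7.64 (edgeR unadjusted p = 0.0499), so its fold is not usable. The smallest p belonged to Scand1 (0.95 ± 0.20), Plin4 (1.21 ± 0.26, 7.74 ± 1.92 against 3.37 ± 1.33 CPM), Hif3a (0.75 ± 0.16, 4.62 against 2.74 CPM), Dcdc2a (−0.48 ± 0.11) and Uaca (−0.49 ± 0.12), all with an adjusted p of 1. Leaving out cKO contralateral library 3 gave 2 calls, Xdh and Gm45837, and leaving out wt contralateral library 2 gave 1, Gm20458, all named after their values were seen.

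On this side too camera's preset correlation, but neither an estimated one nor fry (adjusted p = 0.963), called glucocorticoid targets as higher in cKO. Of 20, 17 were higher, and Plin4, Fkbp5 (0.47 ± 0.14), Lcn2 (2.28 ± 0.72) and Cdkn1a (0.25 ± 0.08), named after their values were seen, passed adjusted over the list alone (median 0.15, camera adjusted p = 5.05e-06; adjusted p = 0.566 with an estimated correlation). The call was lost without cKO contralateral library 2 (camera adjusted p = 0.0502). This call may not be independent of the ipsilateral one, since the labels do not say whether both sides came from the same mice. The median was smallest without wt contralateral library 1 (0.05), was also under 0.1 without cKO contralateral library 1 or 2, and was highest without wt contralateral library 2 (0.23). Of 15 meningeal and fibroblast markers 14 were lower (median −0.29, camera adjusted p = 4.16e-08; adjusted p = 0.566 with an estimated correlation). Camera called 6 further lists, none of them with an estimated correlation (adjusted p = 0.566 or 0.844) and each lost without at least 1 library. Erythroid genes were lower in 9 of 10 cases (median −0.91; lost without cKO or wt contralateral library 1, highest camera adjusted p = 0.63) and monocyte markers in 11 of 17 (−0.35; lost without cKO library 1 or wt library 3, 0.436). Endothelial and mural markers were lower in 15 of 18 cases and stress response genes higher in 14 of 17, both lost without cKO or wt contralateral library 3 (highest 0.684 and 0.755). Cytokines and NF-kB targets were lower in 17 of 29 cases (lost without cKO library 1 or 2 or wt library 2 or 3, highest 0.35). Chemokines were lower in 8 of 14 cases (lost without cKO library 2 or wt library 2 or 3, highest 0.344). Their levels were uneven, near the detection floor in some libraries and above it in others: Ccl3 had 0.138, 1.55 and 0.748 CPM in wt libraries 1 to 3 and 0.0881, 0 and 0.714 CPM in cKO libraries 1 to 3. Mitochondrially encoded genes had a median of −0.12, a mean of 0.03 and a camera adjusted p of 0.689 upwards.

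The last comparison tests whether the injury response itself differed between genotypes. No gene passed with edgeR (0 of 16836; 381 at an unadjusted p under 0.05, 2.26%), DESeq2 or limma-voom, and limma on TPM called 1. The 381 became 903, 631 and 252 without wt contralateral library 3, 1 and 2. Without the filter edgeR called 72. The smallest p belonged to mt-Atp6 (−0.87 ± 0.21), Gm20427 (−1.39 ± 0.34), the scavenger receptor gene Msr1 (3.33 ± 0.83), Eaf2 (−2.58 ± 0.70) and mt-Co2 (−0.72 ± 0.20), all with an adjusted p of 1. mt-Atp6 shares reads with the overlapping mt-Atp8 and mt-Co3, and Gm20427 with H2-Ke6 and Slc39a7. Mitochondrially encoded genes rose less in cKO by camera's preset correlation (median difference −0.28, 11 of 13 negative, camera adjusted p = 1.13e-06; adjusted p = 0.653 with an estimated correlation). Neutrophil markers (median 0.33, camera adjusted p = 0.0688) and immediate early genes (camera adjusted p = 0.85) did not differ past the test. In simulated libraries of this depth the test recovered 67.2% of 2-fold and 29.9% of 1.5-fold differences of response, so smaller ones would often be missed. The simulation changed many genes at once, all at 1 CPM or more, and gave libraries no shared structure. These shares can therefore be too high for the real libraries.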

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

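For 9 gene lists camera called a difference of the injury response between genotypes with its preset correlation, and none of these calls held with an estimated correlation or by fry. The tests of one library and handling, and the margins used for the mitochondrial share and the nuclear copies (first 2 SE, then 1 SE), were chosen only after results were seen. The GC and length, covariate and nuclear copy tests were set before their values were computed, though after the patterns were seen.

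A smaller rise in cKO was called for mitochondrially encoded genes (camera adjusted p = 1.13e-06; 0.653 with an estimated correlation). Larger rises in cKO were called for chemokines (0.00162; 0.673 with an estimated correlation), cytokines and NF-kB targets (0.00162; 0.673), heat shock genes (0.00162; 0.653), monocyte and macrophage markers (0.00337; 0.673), glucocorticoid targets (0.0217; 0.673) and reactive astrocyte genes (0.0297; 0.673). Smaller values in cKO were called for homeostatic microglia markers (0.0217; 0.701) and striatal markers (0.0248; 0.673). In contralateral libraries 1 to 3 the chemokine list mean was −0.584, −0.775 and −0.101 log2 CPM in cKO and −0.965, 0.401 and 0.375 in wt. In ipsilateral libraries it was 2.96, 2.79 and 2.68 in cKO and 2.51, 2.94 and 2.59 in wt. The larger chemokine rise therefore came in part from the contralateral side, where the wt values were uneven. The highest contralateral values (0.401 and 0.375) and the lowest (−0.965) were all in wt libraries.

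All but the mitochondrial call were lost when a single library was left out. Chemokines were lost without wt contralateral library 2 or 3 (highest camera adjusted p = 0.127), cytokines without cKO ipsilateral library 1 (0.199) or wt contralateral library 3, and heat shock genes without wt ipsilateral library 1 (0.053). Monocyte markers were lost without cKO contralateral library 1, cKO ipsilateral library 2 (0.213) or wt ipsilateral library 1. Microglia markers were lost in 5 such fits (0.697), glucocorticoid targets in 6 (0.918), striatal markers in 7 (0.563) and reactive astrocyte genes in 7 (0.509).

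Camera's preset correlation called glucocorticoid targets as higher in cKO than in wt ipsilateral cortex (median log2 0.26), a call lost with an estimated correlation (adjusted p = 0.3) and by fry (0.295). A GC and length trend (median 0.245 with it removed) does not account for the preset call. Leaving out any single library did not end it (highest camera adjusted p = 4.91e-06). That cannot exclude a single library as the source, because the preset correlation takes the genes as nearly independent. The mitochondrial share is argued against as the whole cause, though only by a margin of 1 SE: with it as a covariate the median was 0.365 (camera adjusted p = 1.33e-13) and the list mean 0.44 ± 0.22, against 0.34 ± 0.17 without it, where the share as cause would need under 0.5 of the latter, a bound passed by more than 1 SE but less than the 2 SE first asked for, which would leave the share open. In contralateral cortex the call was lost without cKO contralateral library 2 (camera adjusted p = 0.0502). That cannot show whether 1 library was the source, because fewer libraries also lower the power and the value lies next to 0.05. Handling or time of collection, which can raise corticosterone, cannot be told apart from genotype: 2 of the cKO ipsilateral libraries lay above every wt one, and the labels name no handling group.

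Camera's preset correlation called a smaller rise of mitochondrially encoded genes in cKO (median −0.28), a call lost with an estimated correlation (adjusted p = 0.653) and by fry (0.814). Reads shared with nuclear copies do not account for it: genes and copies summed gave −0.28 ± 0.18, and adding the copies moved the difference by −0.02 ± 0.05, where removing 0.5 of it needs 0.129. The median was −0.227 with GC and length trends removed, so these trends do not account for the whole difference. Leaving out 1 library at a time did not end the preset call (highest camera adjusted p = 0.00948). That cannot exclude a single library as the source, because the preset correlation takes the genes as nearly independent. The difference may still be no more than spread between libraries, since the summed genes differed by −0.26 ± 0.18. How much of the struck tissue each piece held was not recorded in the labels and could not be tested.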

How the results depend on the processing

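Counts of called genes moved with the filter, the test and single libraries. The cause was not tested unless stated. In wt, edgeR called 491 genes after injury, 991 with no low-count filter, 755 with DESeq2, 139 with limma on TPM, 785 with GC and length trends removed and 968 without cKO ipsilateral library 3 and wt contralateral library 3. Leaving out 1 library gave 250 (without wt contralateral library 2) to 861 (without wt contralateral library 3). In cKO, 461 genes became 968 with no filter and 174 with limma on TPM, and leaving out 1 library gave 277 (without cKO ipsilateral library 2) to 436 (without cKO ipsilateral library 3).

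Between genotypes in ipsilateral cortex, 0 calls became 223 with no filter, 12 with DESeq2 and 1 with limma on TPM, and stayed at 0 to 0 with each library left out. In contralateral cortex, 0 became 96 with no filter and 1 with DESeq2, and leaving out 1 library gave 0 (without cKO contralateral library 1) to 2 (without cKO contralateral library 3). The difference of responses went from 0 to 72 with no filter and 1 with limma on TPM, and stayed at 0 to 0 with a library left out. Without the filter 29438 genes were tested and edgeR's prior degrees of freedom went from 6.66 to infinite. Each gene's own estimate of spread was then replaced by a trend fitted over all genes. Other splits of the same ipsilateral libraries then gave 57 to 169 calls, and of the contralateral ones 38 to 591.

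With the replicate block, 567 genes were called in wt, 533 in cKO and 0 in the other comparisons. The wt calls of the striatal list and of 4 named genes (Myoc, Igkc, Acsbg1 and Hba-a2) were lost with the replicate block, and no named cKO call was. Over all alternatives, 119 tests of named genes in wt and 111 in cKO lost a call, and 1133 and 1106 came out the same, which includes genes without a call.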

Other observations

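The genes named here, the splits and the tests of blood content and swapped labels were chosen only after results were seen.

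Of 329 genes called the same way after injury in both genotypes, 216 lay outside every gene list, 211 rising and 5 falling. No theme was tested among these 216. Examples are the complement receptors C5ar1 (log2 3.46 ± 0.20 in wt, 3.98 ± 0.21 in cKO) and C3ar1 (2.71 ± 0.15, 3.01 ± 0.16), the fatty acid receptor Gpr84 (3.89 ± 0.30, 5.03 ± 0.34) and Tlr2 (2.90 ± 0.35, 3.40 ± 0.36). Further examples are genes whose products destroy cytokine mRNA, Zfp36 (2.73 ± 0.13, 2.84 ± 0.13) and Zc3h12a (2.92 ± 0.18, 2.96 ± 0.18). Acod1, which makes itaconate in activated macrophages, was at 1.40 CPM against 0.0461 CPM in wt and 1.91 against 0.0142 CPM in cKO. Tubb1, the tubulin of platelets, was at 0.715 ± 0.393 against 0.0115 CPM in wt and 0.415 ± 0.177 against 0 CPM in cKO.

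The 6 libraries of a comparison can be divided into groups of 3 in 10 ways, the real one included, and 10 splits cannot give a share under 0.05. For the difference of responses, over 12 libraries, 10 splits were used as well, in which both sides of equal number moved together. In wt the real split gave 491 calls and the highest other 1, so 1 of 10 reached the real number. In cKO it was 461 against 0, again 1 of 10. Between genotypes the real number was 0, which 10 of 10 splits reach whatever the data, so the splits decide nothing there, with a highest other of 1 in ipsilateral and 5 in contralateral cortex and 0 for the difference of responses.

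In contralateral cortex, setting cKO libraries 1 and 2 with wt library 3 against the rest gave 2621 genes at an unadjusted p under 0.05, where the genotypes gave 455, which points to a structure of the samples. Its log2 changes followed GC content (rank correlation −0.389) and length (0.373), and with these trends removed the highest other split still gave 1519, so they may account for part of it but not the whole. The amount of blood in the tissue cannot be told apart from it: the erythroid list mean was at most 2.91 log2 CPM in these 3 libraries and at least 4.34 in the others, but 6 libraries are too few to decide. Swapped labels do not account for it: Tmem173 was at 3.18 CPM in wt contralateral library 3, above the highest cKO contralateral library (1.96 CPM). What divides these libraries is not given in the labels.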
